A study of Mus musculus with 6 samples.

How the data were processed

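Mouse brain RNA was sequenced after RNase R digestion, in 3 samples with intraperitoneal 4-aminopyridine and 3 untreated samples, per the labels' protocols. The series' design text speaks of paired tissue, but no label says what samples with the same replicate number share, nor whether each came from a separate animal; p-values therefore measure the spread between these samples.

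The authors deposited 1 table of whole-number read counts per gene for each sample, with 55604 versioned Ensembl identifiers. Reads had been aligned with STAR 2.5.3a and counted with featureCounts on mm10, per the submitters' processing notes. The annotation release, the strand setting and the treatment of multi-mapping reads are not given in the sources used here. A gene-level counter adds up back-spliced and linear reads that fall on exons, so the counts do not measure a single circular RNA. Some genes known to be expressed in brain, among them Rims1, Cdr1, Jund and Egr2, had 0 counts in every library. The sources used here do not show why, so 0 counts in every library are not read as absence of the RNA. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. Of the 21 genes named for the size of their change or as the gene of the series' title, 0 shared more than 20% of their exonic bases with another gene in either orientation.

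Identifiers were matched without their version to GENCODE M21, an annotation of the same assembly; 54723 matched, 53861 of them with the version, and the 881 others held 0.02% of all counts. Coordinates are 1-based on mm10. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom was 7.79, between 4-AP replicate 2 and control replicate 3. No library therefore looked like a repeated count of another, and each was kept as a replicate. This check cannot show that the samples came from separate animals.

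Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 11388. Counts were scaled by trimmed mean of M-values and tested with edgeR 4.0.16 (quasi-likelihood test, robust dispersion and robust fit, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and the quasi-likelihood F. Printed CPM are counts divided by the scaled library size and multiplied by 1e+06. The biological coefficient of variation was 0.18. A count of 3 corresponded to between 0.778 and 2.19 CPM per library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Shares of counts in a single library have Wilson 95% intervals.

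Before the data were examined, 31 gene lists were fixed for seizure-induced genes, reactive glia, cell types, brain regions, ion channels and receptors, IGF signalling, stress responses, circular RNA hosts and RNA classes. The 28 lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. fry tests whether a list's genes move on balance in one direction or, as a mixed test, in either, and does not compare the list with other genes; it called 1 list in one direction and 9 in either. Each member's p was also adjusted over its list alone.

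The genes to name were set by a rule: Igf1r; the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, with a mean log2 CPM of at least 1 and an established symbol; and up to 2 members per list and direction with the smallest p (4 for immediate early genes). Genes outside it are marked where they appear, and a few genes that the rule names are not reported here.

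The procedure was tested on simulated counts with the real means, library sizes and dispersions, in 10 draws with 200 changed genes each among 11388. It recovered 10.7% of genes changed 1.5-fold, 50.7% of those changed 2-fold and 88.2% of those changed 4-fold, and 10.2% of its calls were unchanged genes. A simulated list of 20 genes shifted 1.5-fold was called in all 10 draws, and 0 of 27 unshifted lists per draw were called. Simulated genes were drawn independently of each other, so this does not show how often lists of correlated genes are called wrongly. In the real data the estimated inter-gene correlation ran from -0.0847 (hippocampal markers) to 0.944 (striatal markers), with 0.215 for the immediate early genes.

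Alternatives were other scalings (relative log expression, upper quartile, total counts), DESeq2 1.42.0, limma-voom, no filter on low counts, a CPM above 1 in 3 libraries, mitochondrial, ribosomal and structured RNA genes left out, the replicate number as a block, a loess offset on GC content and length (span 0.5), no robust fit, an adjusted p under 0.1 and each library left out in turn. Added after seeing the data were ribosomal RNA genes and 4 further abundant loci left out, the ribosomal RNA share as a covariate, and replicate 1 of both groups left out. Single values were compared between groups by two-sided exact permutation tests, for which 3 against 3 samples allow no p under 0.1. Circular RNA junctions were not analysed here.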

Results

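Gene-level read counts were obtained from 6 libraries of C57BL/6 mouse brain RNA: 3 from mice injected intraperitoneally with 4-aminopyridine and 3 from untreated controls. 4-Aminopyridine (4-AP) blocks voltage-gated potassium channels and was used here to induce status epilepticus, a prolonged seizure state. The total RNA had been treated with RNase R, an exonuclease that degrades linear RNA and spares circles. The counts combine all reads of a gene, so a change in them cannot be assigned to its circular or its linear RNA. Total counts were 1839831, 2721287 and 1507882 in the 4-AP libraries and 2828471, 3409055 and 2355610 in the controls. The difference in mean depth had p = 0.2 by a two-sided exact permutation test, which with 3 against 3 libraries cannot go below 0.1. The labels do not say which part of the brain was taken.

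The comparison of 4-AP with control brain asked which genes differ in the RNase R-treated RNA after induced seizures. The largest rises included those of hypothalamic hormone genes. Oxt, which encodes oxytocin, had 36 counts over the 3 4-AP libraries and 0 over the 3 controls, at least 19.5-fold higher against a floor of 3 counts over the control group. Avp, which encodes vasopressin, had 77 counts against 3, a ratio of 41.8 (95% counting interval 13.8 to 207). Trh, the thyrotropin-releasing hormone gene, averaged 20.6 ± 2.12 CPM (read count scaled to library size) in 4-AP brain and 1.33 ± 1.12 in control brain (SD, n = 3 each). The genes that fell included the vesicular glutamate transporter Slc17a7, at 558 ± 116 CPM against 964 ± 31.1, and the activity-regulated gene Ier5, at 38.9 CPM against 85.4. Of 11388 genes tested, 38 were higher and 58 lower in 4-AP brain at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In each of these 96 genes all 3 4-AP libraries lay on one side of all 3 controls, as 18.8% of all tested genes did and 10% would by chance. Scaling by total counts alone gave 26 higher and 293 lower genes and moved the median of all genes to -0.22 on the log2 scale, so directions are given relative to the bulk of genes.

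**Figure D1:**
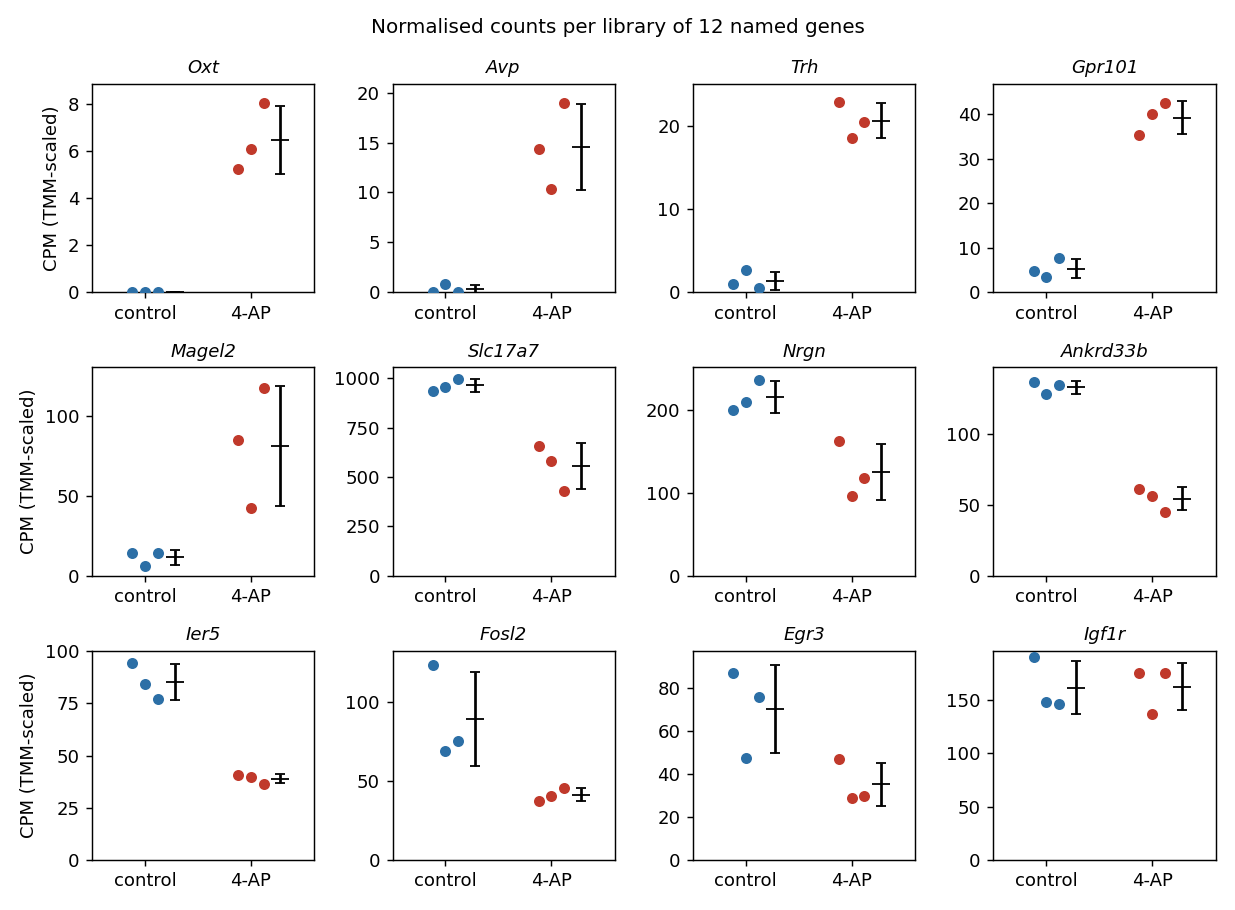
Normalised read count (CPM, y axis, linear, from 0) of 12 named genes in the 3 control (blue) and 3 4-AP (red) libraries; horizontal bars are group means and error bars 1 SD. Oxt was at 0 in each control library, Gpr101 averaged 39.2 CPM in 4-AP brain against 5.22 in control brain, and Igf1r averaged 163 against 162.

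Among the 10 genes with the largest rises, Gpr101, an orphan G protein-coupled receptor on chromosome X (57496668 to 57503757, mm10), had the smallest adjusted p: its log2 fold change was 2.97 (SE 0.29), from 5.22 ± 2.15 to 39.2 ± 3.66 CPM (SD, n = 3 each; adjusted p = 1.86e-05 by edgeR's quasi-likelihood test). Oxt (adjusted p = 0.00349) and Avp (adjusted p = 0.000237, same edgeR test) are neighbours on chromosome 2, at 130576173 to 130577054 and 130580620 to 130582554. The insulin receptor substrate Irs4 rose by 4.20 and Arhgap36 by 4.02 on the log2 scale. Magel2, an imprinted gene of the Prader-Willi region, rose by 2.82 (81.3 against 11.5 CPM). AW551984 rose by 2.73, the GABA-A receptor theta subunit gene Gabrq by 2.43 and the neuronal globin Ngb by 2.22. Several of these genes carried few reads, Gabrq averaging 8.51 CPM in 4-AP and 1.59 in control brain. When each library was left out in turn, Oxt, Avp, Arhgap36, Trh, Gpr101 and AW551984 passed the test in all 6 fits. Irs4, at 8.48, 3.93 and 28.5 CPM in the 4-AP libraries, lost its call without 4-AP replicate 3 (log2 3.10), control replicate 2 (3.76) or control replicate 3 (4.06), and was at 5.08 without control replicate 1. Arhgap36 ranged from 3.44 without control replicate 1 to 4.82 without control replicate 3, and Trh went from 3.76 to 4.72 without control replicate 2. All 3 control counts of Avp were in control replicate 2. The call was also lost for Magel2 without 4-AP replicate 1 or control replicate 3. Ngb lost it in 4 of the 6 fits and Gabrq in 5.

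The 10 genes with the largest falls changed less. Kirrel2, an adhesion protein gene of the nephrin family, fell by 1.83 on the log2 scale, from 15.3 to 4.07 CPM, and the anthrax toxin receptor gene Antxr1 fell by 1.63. Ankrd33b had the smallest adjusted p of the falls (0.000262 by edgeR's quasi-likelihood test), with a log2 fold change of -1.29 (SE 0.17), from 133 to 54.4 CPM. Sowahb fell by 1.45, Stac2 by 1.38, Exph5 by 1.20, the secreted Dickkopf-family gene Dkk3 by 1.19, the bZIP repressor Jdp2 by 1.16 and the VIP and PACAP receptor Vipr1 by 1.16. Hist1h3i, at -1.36, belongs to a family of near-identical histone genes between which reads can be split, so its value is uncertain. Sowahb and Ankrd33b passed in all 6 fits that left out 1 library, whereas Antxr1 and Vipr1 passed in 1, Kirrel2, Exph5 and Jdp2 in 2, Hist1h3i in 3, and Stac2 and Dkk3 in 4.

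The number of called genes depended on single libraries. There were 23 higher and 29 lower genes without 4-AP replicate 1, 91 and 36 without 4-AP replicate 2, 16 and 10 without 4-AP replicate 3, 105 and 54 without control replicate 1, 17 and 24 without control replicate 2, and 27 and 10 without control replicate 3. Of the 96 genes, 17 passed in all 6 of these fits, 13 higher and 4 lower.

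Igf1r, the insulin-like growth factor 1 receptor gene whose circular RNA the series is about, did not differ as a gene-level count. On chromosome 7 (67952827 to 68233668, plus strand), it had 163 ± 22 CPM in 4-AP brain and 162 ± 25 in control brain (SD, n = 3 each), a log2 fold change of 0.002 (SE 0.16; adjusted p = 0.998 by edgeR's quasi-likelihood test). This value is not the level of its circular RNA, for which back-splice reads are needed; these were not analysed here. None of the 19 measured genes of the fixed IGF signalling list passed the test, and the list as a whole was not called (camera adjusted p = 0.256). Shc1 had the smallest p of the positive members (log2 0.59) and the binding protein Igfbp4 of the negative ones (-0.65). The list did not include the insulin receptor substrate Irs4, which rose by 4.20 and passed in 3 of the 6 fits that left out 1 library.

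Of 28 gene lists with at least 5 measured members, 7 differed from the other genes by camera with a preset correlation. The strongest was the list of thalamic, hypothalamic and hindbrain markers (higher; adjusted p = 2.89e-13, and adjusted p = 0.0362 with an estimated correlation). It had 9 measured members with a median log2 fold change of 1.26, of which Oxt, Avp and Trh rose; 4 passed when adjusted over the list alone, the fourth being the catecholamine enzyme Th. The members that rose encode hypothalamic hormones; the thalamic markers Prkcd (log2 0.93, SE 1.11) and Rgs16 (0.84, SE 0.64) did not pass, and the pituitary and hypothalamic precursor Pomc was at -0.60 (SE 1.14). This was the 1 list that held with an estimated correlation, and it was called in each of the 6 fits that left out 1 library.

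**Figure D2:**
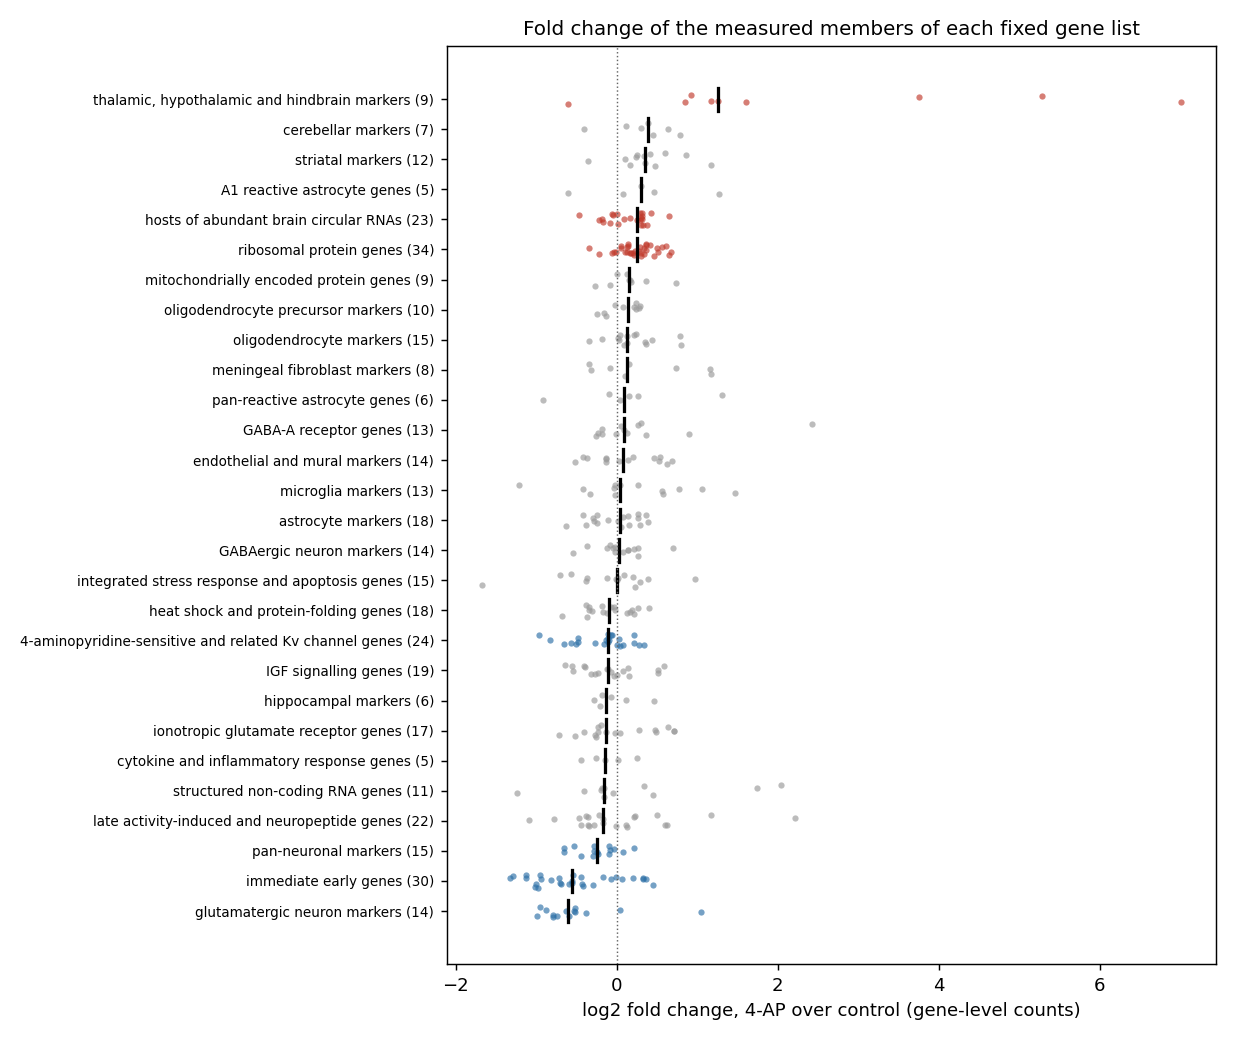
Log2 fold change (x axis, 4-AP over control) of each measured member (points) of the 28 tested gene lists, with the number of members in brackets and black bars at list medians; red lists were called higher and blue lists lower by camera with a preset correlation, grey lists were not called. The thalamic, hypothalamic and hindbrain markers have the highest median (1.26) and the glutamatergic neuron markers the lowest (-0.61).

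Glutamatergic neuron markers were lower in 4-AP brain (median log2 fold change -0.61; camera adjusted p = 5.13e-09). The call was lost with an estimated correlation (adjusted p = 0.302). Of 14 measured members, 3 fell, namely Slc17a7 (-0.79), the calmodulin-binding postsynaptic protein gene Nrgn (-0.79) and the transcription factor Neurod2 (-0.96), the last outside the naming rule; 9 were lower when adjusted over the list alone. Of the 6 fits that left out 1 library, Slc17a7 passed in 3 (highest adjusted p = 0.150 by edgeR's test) and Nrgn in 2 (highest adjusted p = 0.188). Slc17a6, the glutamate transporter gene typical of subcortical neurons, was at 1.05 (SE 0.82) and did not pass. Without control replicate 1, where it was at 38.03 CPM against 5.19 and 10.7 in the other controls, it was higher by 2.31 (adjusted p = 0.00163 by edgeR's test). The 15 pan-neuronal markers were also lower as a list (median -0.25; camera adjusted p = 0.00742, and adjusted p = 0.302 with an estimated correlation), with no member passing over all genes and 3 lower over the list alone; Rbfox3 and Syn1 were both at -0.65, and Syn1 passed without 4-AP replicate 1 (-0.90). The pan-neuronal call was lost without 4-AP replicate 2 (adjusted p = 0.0878 by camera).

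Immediate early genes, the transcripts that neuronal activity induces within minutes, were lower and not higher in 4-AP brain. The time from injection to sampling is not stated here, so an earlier rise is neither shown nor excluded. The median of the 30 measured members was -0.55, 24 lay below 0, and camera gave an adjusted p of 2.13e-08 with the preset correlation and an adjusted p = 0.302 with an estimated correlation. Ier5 (-1.13, SE 0.18) and the AP-1 subunit gene Fosl2 (-1.12, SE 0.22) fell, and 12 members were lower when adjusted over the list alone. Egr3, at -1.0 (adjusted p = 0.0548), and Egr4, at -0.94 (adjusted p = 0.0552), did not pass edgeR's quasi-likelihood test; Egr3 passed without 4-AP replicate 1 or control replicate 2, and Egr4 without control replicate 2. No member rose; Dusp1 (0.37), Rgs2 (0.32), Btg2 (0.33) and Jun (0.21) were the positive members with the smallest p. Ier5 kept its call in all 6 fits that left out 1 library, and Fosl2 lost it without 4-AP replicate 1 or 4-AP replicate 3. Late activity-induced and neuropeptide genes were not called as a list (22 members; camera adjusted p = 0.936), and no member passed over all genes. Scg2 was at 0.63 (adjusted p = 0.0577 by edgeR's quasi-likelihood test, and 0.0485 without 4-AP replicate 2) and Baiap3 at 2.22 (SE 0.53). Over the list alone Scg2 was higher (adjusted p = 0.0135 by edgeR's test), and fry's mixed test called the list (adjusted p = 0.0223).

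Of the channel and receptor lists, the voltage-gated potassium channel genes, which include targets of 4-AP, were lower (24 members, median -0.11; camera adjusted p = 0.0297, and adjusted p = 0.302 with an estimated correlation). When adjusted over the list alone, 6 members were lower; Kcna2 was at -0.48 (SE 0.14) and Dpp6 at 0.28 (SE 0.16), and neither passed over all genes. The list lost its call without 4-AP replicate 1, 4-AP replicate 2, control replicate 1 or control replicate 3 (camera adjusted p between 0.0562 and 0.0878), and without replicate 1 of both groups (0.146). Ionotropic glutamate receptor genes were not called (17 members; camera adjusted p = 0.977): Grin2a, the NMDA receptor subunit GluN2A, fell (-0.71, SE 0.14; called in 4 of the 6 fits that left out 1 library), while Grin3a (0.72) passed only without control replicate 1 (1.01) among the fits that left out 1 library, and 4 members were higher and 2 lower over the list alone. GABA-A receptor genes were not called either (13 members; camera adjusted p = 0.183), with Gabrq the 1 member that rose; with no filter on low counts this list was called higher (adjusted p = 0.0301).

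Hosts of abundant brain circular RNAs (23 members, median 0.25; camera adjusted p = 0.0409) and ribosomal protein genes (34 members, median 0.25; camera adjusted p = 0.000855) were higher as lists. Neither held with an estimated correlation (adjusted p = 0.302 and adjusted p = 0.631, respectively), and no member of either passed alone. The listed hosts Cdr1 and Rims1 had 0 counts in each library, so the list test does not cover them. Among the hosts, Cdyl was at 0.42 (0.65 and called without 4-AP replicate 2), Hipk3 at 0.38 and Homer1 at -0.47. Of the ribosomal protein genes 29 lay above 0, Rpl11 at 0.65 and Rps3 at 0.37. The hosts lost their call without 4-AP replicate 1 (camera adjusted p = 0.216), control replicate 2 (0.0605) or control replicate 3 (0.0562), and the ribosomal protein genes without control replicate 1 (0.109). Scaling by total counts alone also ended the hosts' call (median 0.038; camera adjusted p = 0.253). Relative to the median of all genes, however, the hosts' median was 0.25 with that scaling and 0.26 in the main fit. Without replicate 1 of both groups neither list was called (camera adjusted p = 0.163 for the hosts and 0.457 for the ribosomal protein genes).

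By edgeR's test over all genes and by camera, genes of reactive glia and inflammation showed no called change at this depth. When edgeR's p was adjusted over the list alone, Amigo2 of the A1 list was higher (adjusted p = 0.0387). So were the microglia markers Cx3cr1 (0.00916) and Ctss (0.0305). Gfap, the intermediate filament of reactive astrocytes, was at 0.26 (SE 0.49; adjusted p = 0.891 by edgeR's quasi-likelihood test), and of the pan-reactive list only 6 of 13 members had enough counts to test (camera adjusted p = 0.815). The A1 reactive list had 5 measured members (camera adjusted p = 0.368), with Amigo2 at 1.27 and H2-T23 at -0.60, and the A2 list 2, Ptgs2 at -1.09 and Sphk1 at -0.87, too few for a list test. Cytokine and inflammatory response genes had 5 measured members of 27 (camera adjusted p = 0.895); Tnf, Il6 and Ccl2 had 0 counts in each library and Il1b at most 1, so a change in them was not detectable. Microglia markers (13 members; adjusted p = 0.256) were not called, but were called higher without 4-AP replicate 3 (0.0425) or control replicate 2 (0.0483), with Cx3cr1 at 0.57 and Siglech at -1.21. Astrocyte markers (18 members; adjusted p = 0.760) were not called as a list, but the glutamate transporter Slc1a2 fell by 0.63 on the log2 scale, from 1748 to 1132 CPM. Slc1a2 passed in 2 of the 6 fits that left out 1 library (highest adjusted p = 0.210 by edgeR's test).

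The remaining lists were not called by camera: GABAergic neuron markers (adjusted p = 0.576), oligodendrocyte markers (0.256), oligodendrocyte precursor markers (0.576), endothelial and mural markers (0.660), meningeal fibroblast markers (0.335), hippocampal markers (0.895), striatal markers (0.102), cerebellar markers (0.368), heat shock and protein-folding genes (0.306), integrated stress response and apoptosis genes (0.895), mitochondrially encoded protein genes (0.523) and structured non-coding RNA genes (0.95). No gene of these lists passed the test. The striatal result depended on the setting: the list was called higher with total counts only (adjusted p = 0.00288), limma-voom (0.000449), no filter on low counts (0.00222), and without control replicate 2 (0.0483) or control replicate 3 (0.000116). Its median went from 0.35 to -0.12 without control replicate 1. Oligodendrocyte markers were called higher without 4-AP replicate 3 (0.0381), control replicate 1 (0.0443) or replicate 1 of both groups (0.00676), and meningeal fibroblast markers without 4-AP replicate 3 (0.0129) or with no filter (0.0368). Choroid plexus and ependymal markers had 4 measured members and blood cell markers 3, too few for a list test. In settings that left at least 5 members, the choroid plexus and ependymal markers were called higher with no filter (0.00222), with a CPM above 1 in 3 libraries (0.00625), and without 4-AP replicate 1 (0.000232), control replicate 1 (0.0288), control replicate 2 (0.0483), control replicate 3 (0.00125) or replicate 1 of both groups (0.00142). Ttr averaged 22.5 ± 28.2 CPM in 4-AP brain and 1.46 ± 1.57 in control brain (SD, n = 3 each), with 55.0 CPM in 4-AP replicate 2. The sign of the median or the mean differed from the direction of the camera test in the hippocampal, astrocyte, late activity-induced, ionotropic glutamate receptor, structured RNA and stress response lists, none of which was called.

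The libraries also differed in composition and in regional markers, in part along the group. Annotated ribosomal RNA genes, without the mitochondrial ones, held 5.86 ± 2.75% of counts in 4-AP libraries and 1.78 ± 1.74% in controls (SD, n = 3 each; two-sided exact permutation p = 0.2, smallest possible 0.1). The gene Lars2 held 16.8 ± 4.49% against 6.71 ± 4.66% (exact permutation p = 0.1). All ribosomal RNA genes, mitochondrial ones included, and 4 further loci with Lars2 among them held 28.3 ± 8.51% against 12.3 ± 7.78% (exact permutation p = 0.2). With the log2 share of ribosomal RNA genes, mitochondrial ones included, as a covariate, edgeR's test called no gene. At an unadjusted p under 0.05 it gave 970 genes, against 1578 without the covariate and 569 expected by chance. The median log2 fold change of the 38 higher genes went from 1.30 to 1.18 and their median SE from 0.21 to 0.31. Control replicate 1 had lower levels than any other library of all 12 measured striatal markers, with Adora2a at 1.26 CPM against a median of 59.98 in the other libraries. Without control replicate 1 and 4-AP replicate 1, the latter low in signal recognition particle RNA at 0.276% of counts (95% Wilson interval 0.269 to 0.284%), 48 genes were higher and 28 lower.

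**Figure D3:**
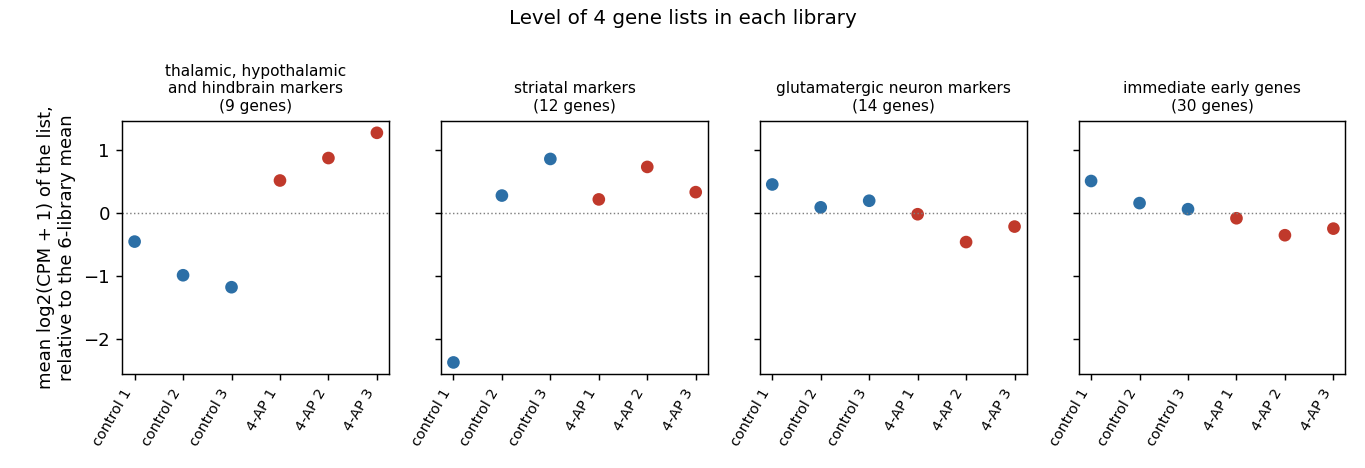
Mean log2(CPM + 1) of 4 gene lists in each of the 3 control (blue) and 3 4-AP (red) libraries, relative to the mean over the 6 libraries (y axis, log2 units). The thalamic, hypothalamic and hindbrain list lies between 0.51 and 1.27 in the 4-AP libraries and between -1.18 and -0.46 in the controls, and the striatal list is at -2.38 in control replicate 1.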

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

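Leaving out ribosomal RNA genes with 4 further loci, the ribosomal RNA share as a covariate and leaving out replicate 1 of both groups were chosen after the data were seen; all other alternatives were set before. Of the 38 higher and 58 lower genes, the number rose to 82 and 111 with DESeq2, to 131 and 197 with no filter on low counts, and to 121 and 169 at an adjusted p under 0.1; it dropped to 25 and 30 without the robust fit. Total counts alone gave 293 lower genes, the GC and length offset 58 higher genes, and leaving out replicate 1 of both groups 28 lower genes. Across the fits that left out 1 library the counts ranged from 16 to 105 higher and from 10 to 54 lower, with fewer samples in each. The ribosomal RNA share as a covariate left 0 higher and 0 lower genes by edgeR. There were 970 genes at an unadjusted p under 0.05, with 569 expected by chance, and no other tool was run with the covariate. All 96 folds kept their sign in that fit, and the median of the lower genes was -0.92 (median SE 0.25) against -0.82 (0.17). Of the 96 genes, 35 higher and 57 lower ones had an unadjusted p under 0.05 by edgeR's test. The 96 were picked from these same counts, so their kept signs and small unadjusted p are not separate support. SEs were larger, with 3 residual degrees of freedom in place of 4. The same fit turned the ribosomal protein genes, with a median of 0.0084 and a camera direction of lower (adjusted p = 0.806; the cause was not tested). It also ended the calls of the potassium channel genes (adjusted p = 0.0642) and the circular RNA hosts (0.215), and called oligodendrocyte (0.00567), endothelial and mural (0.00922) and meningeal fibroblast markers (0.00943) higher. The 7 called lists became 11 with no filter, 1 with an estimated correlation and 1 with fry. Apart from these, causes were not tested. Samples with the same replicate number did not all deviate together (correlations across genes -0.0019, 0.113 and 0.0245 for replicates 1, 2 and 3). The value of replicate 2 was the highest of all pairs between the groups, while 4-AP replicates 1 and 3 correlated better with a control of another number. Whether the samples were paired is therefore not settled. The replicate block gave 112 higher and 153 lower genes, and 83 higher genes with the GC and length offset. It also called the striatal markers higher (camera adjusted p = 0.0138, and 0.0202 with the offset). DESeq2 kept 68 of the 96 genes and gave the other 28 no adjusted p. Of the 20 genes named by the size of their change, DESeq2 called 4 and gave 16 no adjusted p, and limma-voom called 14. Of the 96 genes limma-voom kept 61, the GC and length offset 81 and the unfiltered fit 96. No named gene's call changed direction under any setting. Of simulated 2-fold changes, 12.7% were found among the genes with the lowest mean counts (6 to 34.7 per library) and 86% among those with the highest (over 110), in 3 classes of equal size.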

Other observations

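The tests of the immediate early genes against the glutamatergic markers, of the ribosomal RNA share and of the linear RNA sets were chosen after the results were seen. The tests of further hypothalamic and cortical genes were set after the gene results, but before the values of the listed genes were seen. The other tests were set before. The count of the hypothalamic genes that the filter had removed, the genes named in the next paragraph, Otof, and the markers singled out in control replicate 1 were also chosen after values were seen.

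Beyond the hormone genes, the higher genes that passed in each of the 6 fits leaving out 1 library included the imprinted gene Nnat (log2 1.45, 230.1 against 84.0 CPM), the huntingtin-associated protein gene Hap1 (1.47, 361 against 130.4 CPM), Cdh23 (1.91), the pyrimidine-degrading enzyme Dpyd (1.70), Vat1l (1.29) and Zcchc12 (1.30). Ndn, an imprinted neighbour of Magel2, was higher by 0.80 but did not pass in all 6. Among the lower genes, the calcium-stimulated adenylyl cyclase Adcy1 fell by 1.01, from 1642 to 814 CPM, the neuronal pentraxin Nptx1 by 0.82, the kinase Camkk2 by 0.77 and the transcription factor Mef2c by 0.72; none of these 4 passed in all 6 fits. fry's mixed test, which asks for change in either direction, called 9 lists, among them the GABA-A receptor genes (adjusted p = 0.000508), the ionotropic glutamate receptor genes (adjusted p = 0.0049) and the microglia markers (adjusted p = 0.0223).

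Control replicate 1 stood apart in striatal genes. Drd1 was at 3.77 CPM there against a median of 63.5 in the other 5 libraries, Penk at 8.17 against 116.5 and Ppp1r1b at 27.3 against 160.5. All 12 measured striatal markers lay below the lowest of the other libraries, while glutamatergic markers were higher there than in any other library (0.45 in mean log2 units above the 6-library mean).

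Hypothalamic genes were higher in 4-AP libraries. Induction limited to secreted peptides is argued against: 10 further hypothalamic genes that encode no secreted peptide and passed no test alone had a median log2 fold change of 0.79, with 10 of 10 above 0 and the 95% point of 10000 expression-matched random lists at 0.27, and the median stayed at or above 0.63 when any 1 library was left out. Of 42 such genes listed, 29 others had counts but too few to test, and summed they averaged 62.0 ± 16.2 CPM in 4-AP against 16.9 ± 5.78 in control libraries (SD, n = 3 each; 342 against 155 counts). The list was written after the gene results but before its members' values were seen; Peg3 was at 331 against 274 CPM and Ecel1 at 30.2 against 11.6 CPM. These values are consistent with a larger share of hypothalamic tissue in the 4-AP samples, which may reflect dissection; a response of hypothalamic neurons to 4-AP stays open, since the labels name no brain region.

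Glutamatergic markers and immediate early genes were lower in 4-AP libraries. GC content and length are argued against, since with an offset for them both list medians stayed at or below -0.57. With the ribosomal RNA share as a covariate, the median of the glutamatergic markers was -0.81. It lay between -1.07 without control replicate 3 and -0.51 without 4-AP replicate 2, and so did not move to near 0. The log2 share correlated with the group at 0.758 over the libraries, so this fit separates share and group only in part. Carry-over is therefore not settled for the glutamatergic markers. For the immediate early genes the median with this covariate was -0.38. It went to -1.08 without control replicate 3 and to -0.15 without 4-AP replicate 2, so carry-over cannot be told apart from the treatment there. A smaller share of cortical tissue is a candidate explanation for the glutamatergic markers. The 28 further cortical genes that passed no test alone, listed in the same way, had a median of -0.28, below the 5% point of random lists (-0.14). Their median was -0.18 without control replicate 2 and -0.46 without 4-AP replicate 1. Of the 28, 7 lay above 0, the highest being Otof at 0.56. Cortical genes can vary together between samples, which the random lists do not reproduce. The immediate early median lay 0.052 above the glutamatergic one (between -0.001 and 0.19 with 1 library left out), so tissue share as the whole cause and a lower activity of the neurons cannot be told apart. A difference in the digestion of linear RNA, raised below for the circular RNA hosts, was not tested for either list and stays open as well.

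Hosts of abundant brain circular RNAs were higher in 4-AP libraries, which more complete digestion of linear RNA could give. That would lower genes whose reads are linear, and these moved apart: the ribosomal protein genes had a median of 0.25, above the 95% point of random lists (0.09), while 226 single-exon protein-coding genes had a median of -0.16, below the 5% point (-0.05). Other linear RNAs, picked after values were seen, were split as well. Ribosomal RNA genes held 5.86 ± 2.75% of counts in 4-AP libraries against 1.78 ± 1.74% in controls (SD, n = 3 each; two-sided exact permutation p = 0.2), opposite to more complete digestion. Malat1 was at -0.40 (SE 0.18) and did not pass edgeR's test. The digestion difference and a change in circular RNA therefore cannot be told apart from gene-level counts, and the host list itself lost its call with an estimated correlation.

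The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 38 higher and 58 lower genes; 1 split reached each of these counts, the real one, and the highest count in 1 direction of the other splits was 1 gene. For the 7 called gene lists, 4 splits gave as many, the real one included, and the highest of the others was 9.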
